A study of Homo sapiens with 2 samples.

How the data were processed

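Total RNA from PLC-PRF-5 cells was profiled on 2 Illumina bead arrays, 1 from cells kept with DMSO and 1 from cells treated with 50 μM oleanolic acid (OA), both for 24 h. Per the labels' protocols, RNA was taken up in TRIzol and biotin-labelled cRNA was made with an Ambion MessageAmp kit for Illumina arrays. The deposited table holds an intensity per probe on a linear scale for 47323 probes. The software, the background correction and the normalization are not given in the sources used here. The deposited intensity values themselves show 2 steps. First, the 1st to 99th percentiles of the 2 columns were the same (largest gap 0 on the log2 scale), so the authors' values were already quantile normalized. Second, 30.5% of probes on the DMSO array and 30.9% on the OA array sat at exactly 1, the lowest value, so lower values had been set to 1. The table holds no detection p-values. Quantile normalization removes any difference between the arrays in total signal, and values near 1 carry no order. The number of arrays limits the precision: with 1 array per condition no difference has a replicate check, and no p-value was computed. Nothing in the labels gives a batch, slide or scan for either array, so array and treatment cannot be told apart.

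Probes were named from GEO's annotation of the platform. Of the 47323 probes, 30113 had 1 gene symbol, 8 had several and 17202 had none in that annotation and were left out of the gene analysis. The Entrez ID of 30074 of the 30121 listed probes matched the NCBI gene table of assembly GRCh38.p14, which changed the symbol of 0 probes. Each of the 20046 genes was represented by its probe with the highest mean intensity over the 2 arrays. A background floor was set for each array at the 95th percentile of its 455 olfactory receptor probes, a family not expected in hepatoma cells. The floor was 11.3 intensity units on the DMSO array and 9.56 on the OA array. The brightest olfactory receptor probe reached 67.4 units on the DMSO array and 74.1 on the OA array. A gene was used where it lay above the floor in at least 1 array. The difference is log2(OA) minus log2(DMSO) of the deposited intensities, with no pseudocount. For a gene above the floor in only 1 array, a fold is given as "at least", from the bright value over the other array's floor or own value, whichever is higher. No fold is given where that value lies under the other array's floor, and the lower OA floor makes bounds for lower genes slightly larger than those for higher genes. Since some olfactory receptor probes lie above the floor, such a bound holds against the floor and is not a strict limit.

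Genes were counted by a rule of size, a difference of 2-fold or more. The error of a single gene has 2 internal measures. The local robust SD is the median absolute deviation, scaled to an SD under a normal distribution, of the log2 differences of the 500 genes nearest in mean level, and includes true differences. The probe error is the SD of the difference between the 2 brightest probes of a gene, divided by the square root of 2. Neither covers the spread between cultures. For 26 gene lists fixed before the data were examined, the median log2 difference was taken over the members above the floor. Its percentile is given among 10000 random lists of the same size, matched on mean level in 20 bins. A list was called higher over a percentile of 97.5 and lower under 2.5. Genes of a pathway vary together and random genes do not, so the percentiles describe these 2 arrays and are not p-values. Of 26 lists, 1.3 would lie outside that range by chance if their genes varied independently, which does not hold, and some lists share members.

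The genes named follow a rule that was fixed at the same time. It takes the 12 highest and 12 lowest differences among genes above the floor in both arrays, and the 3 highest and 3 lowest bounds among genes above it in 1 array. It adds the 2 highest and 2 lowest members of each list. It also adds 14 genes tied to the series title and 5 reference genes. Genes outside the rule are marked as chosen after their values were seen. Alternatives covered the normalization, the floor, the choice of probe, an added offset of 32 units, values raised to the floor and the fold threshold. A floor of 100 units, another choice of brightest probe and the list mean with values raised to the floor were added after the data were seen.

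The count rule and the list percentile were tested on simulated data built from the 9972 genes above the floor in both arrays, with error set by the local SD and 200 genes changed. For the comparison of OA with DMSO, 44% of genes planted at a log2 change of 1 came out at 2-fold or more. The shares were 92% at 1.5, 96% at 2 and 100% at 3. Of the unchanged genes 2.78% passed the 2-fold rule, and 0.204% of those with a mean level of 100 units or more. These rates do not cover genes above the floor in only 1 array, which made up 1477 of the 1822 genes past 2-fold. Of 200 random lists of 30 genes, 3.5% were called, and 96% of 100 lists shifted by 0.3 were called higher. The simulated error was independent between genes, so these shares do not cover lists whose genes vary together. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.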

Results

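Gene expression was compared between PLC-PRF-5 cells, an established human hepatoma line, after 24 h with 50 μM oleanolic acid (OA) and after 24 h with DMSO. The identity of the cells was not tested here. Only 12 of 47 hepatocyte genes lay above the background floor, and AFP was under it on both arrays, so the label stays unchecked. OA is a plant triterpenoid. The series title sets the comparison in the context of the epithelial to mesenchymal transition, in which epithelial cells take on a motile, matrix-producing state, and of inducible nitric oxide synthase. Each condition had 1 array, so every value below is a single measurement without replicates. Of the probes 39.1% lay above the background floor on the DMSO array and 42.0% on the OA array. Of 20046 named genes, 12007 lay above the floor in at least 1 array and 9972 in both. Over the 16469 probes above the floor in both arrays the log2 values correlated with r = 0.979. That correlation is across probes, which are not independent replicates.

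Among the 12 genes highest in OA relative to DMSO were genes of stress response, amino acid metabolism and chemokines, with others of unlike function. NIBAN1, a stress-induced protein, went from 16.4 units in DMSO to 296 in OA, a log2 difference of 4.17 with a local robust SD of 0.43. Its other probe gave 3.12. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, differed by 2.88 (local SD 0.33), while a second probe gave 1.46 and its last probe lay under the floor on both arrays. TRIB3, a pseudokinase of the integrated stress response, went from 287 to 2027 units (log2 2.82, local SD 0.28). DDIT3, which encodes the transcription factor CHOP, differed by 2.39, and DDIT4, an inhibitor of mTORC1, by 2.07 (local SDs 0.43 and 0.28). The amino acid transporter SLC1A4 and the branched-chain aminotransferase BCAT1 differed by 2.43 and 2.03, from 12.1 and 14.4 units in DMSO (local SDs 0.60 and 0.56). The chemokine genes CCL5 and CXCL2 differed by 2.54 and 2.21 (local SDs 0.34 and 0.39), and a dimmer CCL5 probe went from 1.46 to 89.0 units. The other members of the top 12 were BEX2 at 2.87, PLD1 at 2.17 and NNMT, nicotinamide N-methyltransferase, at 2.12 (local SDs 0.42, 0.63 and 0.36).

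The 12 lowest genes in OA were mostly dim. FGFBP1, a binding protein of fibroblast growth factors, went from 83.6 to 17.3 units (log2 -2.27, local SD 0.59). The prostaglandin E2 receptor genes PTGER3 and PTGER4 differed by -2.27 and -1.80 (local SDs 0.60 and 0.66), with the other 4 probes of PTGER3 under the floor on both arrays, and the drug efflux pump gene ABCG2 by -1.75 (local SD 0.51). TM4SF4 and VAV3 were the brightest of the 12, at 141 and 173 units in DMSO, and differed by -1.75 and -1.67 (local SDs 0.45 and 0.37). A second VAV3 probe gave -1.17, and its last probe went from 1 to 10.2 units, which put the mean over its probes at 0.17. The remaining members were PRKD3 at -1.94, the zinc importer gene SLC39A10 at -1.78, the interferon-induced IFIT1 at -1.77, RLF at -1.72, SEMA6B at -1.69 and VASH2 at -1.67. Among genes above the floor in only 1 array, LCN2, which encodes lipocalin 2, was at least 7.66-fold higher in OA. The BCL2-family gene HRK was at least 5.32-fold higher and TELO2 at least 4.27-fold higher. CACNA1G was at least 4.98-fold lower in OA, PDHA2 at least 3.68-fold lower and BAAT, the bile acid conjugating enzyme, at least 3.61-fold lower. Of these genes above the floor in only 1 array, only LCN2, at 86.3 units in OA, was brighter than that array's brightest olfactory receptor probe. The others lay within the range of the olfactory receptor probes.

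By the 2-fold rule 994 genes were higher and 828 lower in OA, out of 12007. Most of these were dim: 1651 of the 1822 had under 50 units on the brighter array, and 1477 lay above the floor in only 1 array. Of the 1477, 848 were higher and 629 lower in OA, and the lower OA floor admits more genes that are higher in OA. With the array medians as the floor, 6.21 units on both arrays, the counts were 1558 higher and 1578 lower. The excess of higher genes thus went with the unequal floors. Among the 5736 genes with 100 units or more on either array, 39 were 2-fold higher and 44 lower, or 1.45% of them. With values under the floor raised to the floor, the counts were 245 higher and 336 lower. After an intensity-dependent loess they were 364 higher and 971 lower, so the share of higher genes went from 54.6% to 27.3%. The probe error measured from 2 probes of a gene was 0.421 for dimmer probes under 50 units (986 genes) and 0.184 at 100 units or more (958 genes). Of 24 other probes of named genes above the floor in both arrays, 20 went the same way as the gene's brightest probe and 13 lay within its local SD. The SD of the differences over the 9972 genes was 0.443 and their median was -0.02.

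**Figure D1:**
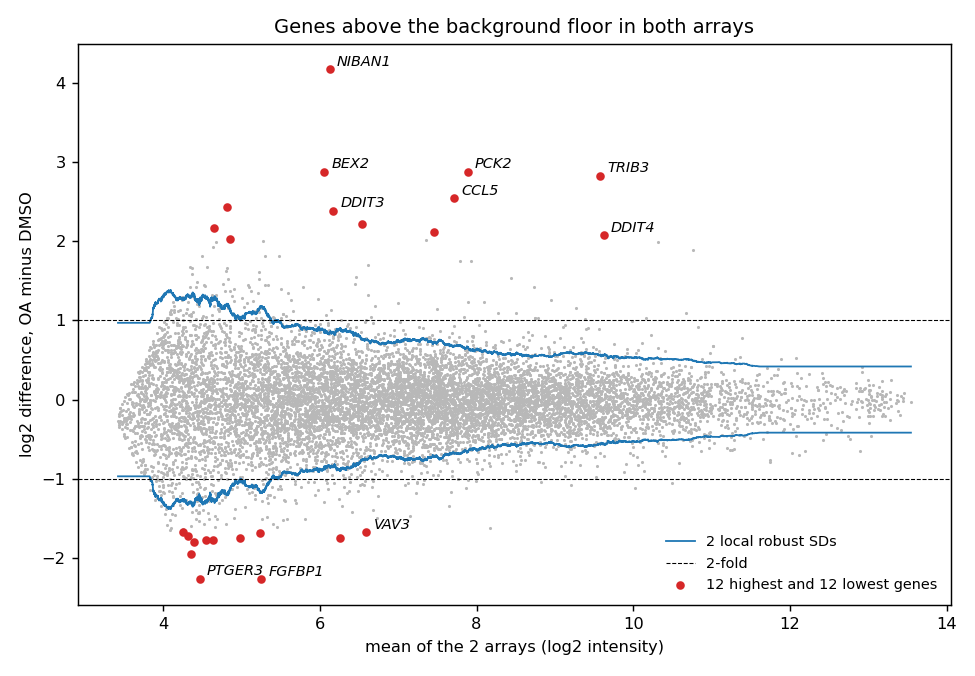
Each point is a gene above the background floor in both arrays, with the mean log2 intensity of the 2 arrays on the x axis and the log2 difference (OA minus DMSO) on the y axis; red points are the 12 highest and 12 lowest genes, blue lines lie at 2 local robust SDs and dashed lines at 2-fold. NIBAN1 at 4.17, PCK2 at 2.88 and TRIB3 at 2.82 lie far outside the blue lines, which widen just above the floor and then narrow toward high intensity.

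Genes of the mesenchymal state were slightly lower in OA as a list, and genes of the epithelial state lay inside the range of random lists. Of 39 mesenchymal genes above the floor, 24 were lower and 15 higher in OA. Their median log2 difference was -0.27, or 1.20-fold, at the 0.11 percentile of random lists. THBS1, the matrix protein thrombospondin 1, went from 210 to 73.1 units (log2 -1.52, local SD 0.36), and the integrin gene ITGAV from 653 to 316 (log2 -1.04). These 2 genes, chosen after their values were seen, were the members with 100 units or more that were 2-fold lower, of 23 such members, and 0 were 2-fold higher. By the 2-fold rule over all 39 members, 5 were lower and 4 higher. The 4 higher ones lay above the floor in OA only, and of the lower ones FAP, COL6A3 and DCN in DMSO only. With values raised to the floor the counts were 3 lower and 0 higher. FAP was at least 2.07-fold lower, and COL6A3, a collagen gene, at least 1.76-fold lower. The list's call ended with each array's median as the floor (percentile 2.67), with no floor (53.5) and with the mean in place of the median (5.3), though not with the mean of values raised to the floor (0.61).

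Of the classical markers of the transition, several were not above the floor, and those above it on both arrays were less than 2-fold apart. CDH1, which encodes E-cadherin, was at 48.9 units in DMSO and 47.1 in OA (log2 -0.05, local SD 0.46). CDH2, which encodes N-cadherin, differed by 0.25 (local SD 0.29). VIM, which encodes vimentin, differed by -0.27 (local SD 0.21), from 7202 to 5974 units, and its other probe gave -0.24. FN1, the fibronectin gene, was near the floor at 14.8 and 9.80 units and differed by -0.59 (local SD 0.48), and TWIST1 differed by 0.05 (local SD 0.60). SNAI1, ZEB1, ZEB2, MMP2 and MMP9 were not above the floor on either array. SNAI2 lay just above the floor in OA only, at least 1.06-fold higher. Of 25 epithelial genes above the floor, 10 were higher and 15 lower, with a median of -0.10 at percentile 18.3. CLDN3, a tight junction gene, was 2.23-fold higher, PKP2, a desmosome gene, was 2.17-fold lower and the protease gene PRSS8 at least 2.11-fold lower. PKP3 went from 7.18 to 12.1 units, at least 1.08-fold higher, and the mesenchymal PRRX1 from 2.99 to 10.2. The difference between the 2 lists was not tested.

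**Figure D2:**
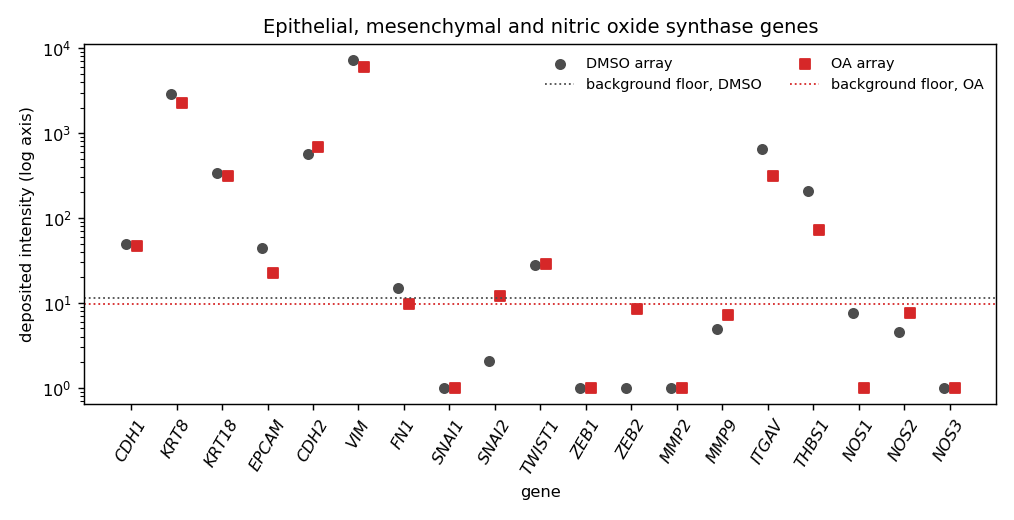
Deposited intensity on a log axis (y) for 19 epithelial, mesenchymal and nitric oxide synthase genes (x), with circles for the DMSO array, squares for the OA array and dotted lines for each array's background floor; KRT8, KRT18, EPCAM, ITGAV and THBS1 were chosen after their values were seen. CDH1 and TWIST1 lie level between arrays, ITGAV and THBS1 are lower in OA, and SNAI1, ZEB1, ZEB2, MMP2, MMP9 and the 3 nitric oxide synthase genes lie under the floor.

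Transcripts of nitric oxide synthases were not detectable above background in either condition. NOS2, which encodes the inducible enzyme, was at 4.52 units in DMSO and 7.67 in OA, and none of its 3 probes lay above the floor. NOS1 and NOS3 were also under the floor on both arrays. Over the 20 measured genes of nitric oxide metabolism, 9 were higher and 11 lower, with a median of -0.04 at percentile 39.5. The mean was 0.28, opposite in sign, or 0.05 with values raised to the floor. GUCY1A1, a subunit of the nitric oxide receptor guanylyl cyclase, went from 1 to 17.3 units, at least 1.53-fold higher. CAV1, which encodes the synthase-binding caveolin 1, differed by -0.79 (local SD 0.21), and its other probe by -0.73. HSP90AA1 differed by -0.38, with other probes at -0.52 and 0.08, and GUCY1A2 went from 5.47 to 13.7 units, at least 1.22-fold higher. The protein state of the enzyme, which the title concerns, is not measured by these arrays.

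Genes of the ATF4 and endoplasmic reticulum stress response, which adapt cells to amino acid shortage and unfolded protein, had the highest list median in OA. Of 52 members above the floor, 46 were higher and 6 lower, and 14 were 2-fold higher and 0 were 2-fold lower. The median was 0.63, or 1.55-fold, above all 10000 random lists, of which 95% lay between -0.12 and 0.08. Besides TRIB3, DDIT3 and DDIT4, members chosen after their values were seen included ASNS, asparagine synthetase, from 640 to 2543 units (log2 1.99, local SD 0.26). PHGDH, the first enzyme of serine synthesis, went from 902 to 3327 units (log2 1.88), and PSAT1, of the same pathway, from 1125 to 2391 (log2 1.09). VLDLR differed by 1.54, XBP1 by 1.16 and ATF4 itself by 0.52. CHAC1 and SESN2 were above the floor in OA only, at least 1.44-fold and 1.61-fold higher. The lowest members were the chaperone genes CALR at -0.67 and HSP90B1 at -0.35 (local SDs 0.29 and 0.24). Among the 42 members with 100 units or more, 10 were 2-fold higher and 0 lower, and with values raised to the floor 12 members were 2-fold higher.

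Inflammatory genes of the NF-kB list were also higher in OA, with a median of 0.40 over 33 members, above all 10000 random lists. Of these 22 were higher and 11 lower, and 8 were 2-fold higher and 1 lower. With values raised to the floor the median was 0.22 and 5 members were 2-fold higher. With no floor, over 42 members, the median was 0.09 at percentile 97.58, barely inside the call. Besides CCL5, CXCL2 and LCN2, the chemokine gene CCL20 was at least 3.25-fold higher. SOD2, mitochondrial superoxide dismutase, chosen after its value was seen, differed by 1.23. CCL2, which encodes a monocyte chemokine, went the other way, from 860 to 407 units (log2 -1.08, local SD 0.30), as did PTGS2, which encodes cyclooxygenase 2, at -0.57 (local SD 0.28). Immediate early genes had a median of 0.23 at percentile 99.4, with 18 of 27 higher. KLF2, chosen after its value was seen, differed by 1.03, EGR1 was at least 1.79-fold higher, and DUSP2 and SPRED1 differed by -0.66 and -0.45. FOS went from 1.49 to 10.2 units.

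Cell cycle genes were lower in OA. Of 66 members above the floor, 57 were lower and 9 higher, with a median of -0.38, or 1.30-fold, below all 10000 random lists. By the 2-fold rule 5 were lower and 0 higher, or 4 and 0 with values raised to the floor, and 20 were 1.5-fold lower. CENPE, a kinesin of the kinetochore, differed by -1.20 (local SD 0.44), and its other probe by -1.04. CDC6, which loads the replicative helicase, was at least 1.51-fold lower. DLGAP5 and CENPF, mitotic genes chosen after their values were seen, differed by -1.02 and -1.01. The highest members were BUB1B at 0.49 (local SD 0.50) and CKS1B at 0.25 (local SD 0.21), whose second probe gave 0.02. The G1 list had a median of -0.26 over 16 genes at percentile 1.07 but a mean of 0.11, which was -0.14 (percentile 14.8) with values raised to the floor. CDKN1A, which encodes the p21 inhibitor, differed by -0.80 (local SD 0.25), and its other probe was under the floor on both arrays. RBL2 differed by -0.94 (local SD 0.37). CCNG2 went from 1.93 to 11.4 units, at least 1.01-fold higher, and CDKN2B from 5.21 to 17.2, at least 1.52-fold higher. The p53 target list had a median of -0.23 over 27 genes at percentile 1.05, which was lost with the mean (percentile 14.8). FAS was at least 1.69-fold lower, SPATA18 at least 1.90-fold lower, and TNFRSF10C went from 4.86 to 12.5 units, at least 1.11-fold higher.

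Genes of the NRF2 oxidative stress response and of the heat shock response were lower in OA by small amounts. Over 34 NRF2 genes the median was -0.22 at the 0.04 percentile, with 26 lower and 7 higher. GPX2, a glutathione peroxidase, went from 1530 to 707 units (log2 -1.11, local SD 0.27). GCLC, which catalyses the first step of glutathione synthesis, differed by -0.78 (local SD 0.28). HMOX1, heme oxygenase 1, and SLC7A11, the cystine transporter, went the other way at 0.68 and 0.61 (local SDs 0.36 for both), and SLC7A11 is also on the ATF4 list. Over 22 genes of the heat shock list, mostly chaperones, the median was -0.26 at percentile 0.21, with 19 lower and 3 higher. CHORDC1 differed by -1.03 on its brightest probe while its other probe went from 1 to 11.2 units, near the floor. DNAJB4 differed by -0.95, HSPB8 by 0.72 and HSF1 by 0.42 (local SDs 0.68, 0.63 and 0.46), and a second DNAJB4 probe by -0.02.

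Lists of ribosomal proteins and of the respiratory chain had slightly higher medians in OA, with members on both sides of 0. The ribosomal median was 0.09 over 66 genes at percentile 99.99, with 46 higher, and 20 were lower and 0 reached 2-fold. RPS7 differed by 0.62, RPL14 by 0.57, RPLP2 by -0.21 and RPL28 by -0.49, and second probes of RPS7 and RPL14 by 0.34 and 0.03. The respiratory chain median was 0.09 over 58 genes at percentile 99.8, with 44 higher and 13 lower. NDUFA10 differed by 0.86 and its other probe by 0.83, NDUFS1 by -1.23 and NDUFC2 by -0.70, and NDUFB4 was at least 1.63-fold higher. Both medians are under the error of a single gene and hold only as list values.

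Most genes of hepatocyte secreted proteins and regulators lay under the floor. ALB, the albumin gene, was at 30.6 units in DMSO and 29.1 in OA, AFP was under the floor on both arrays, and so was the bile acid receptor gene GPBAR1. Only 12 of 47 hepatocyte genes lay above the floor, with a median of -0.34 at percentile 3.10. CEBPA, a liver transcription factor, differed by 1.18 (local SD 0.37) and PROC by 1.03 (local SD 0.68), while APOH was at least 3.59-fold lower and ITIH1 at least 2.16-fold lower. The 13 genes of xenobiotic and bile acid metabolism had a median of -0.40 at percentile 0.37, with 10 lower, but a mean of -0.18 at percentile 28.1, or -0.50 with values raised to the floor. Besides BAAT, the uptake transporter SLCO1B3 differed by -0.94 (local SD 0.43), and UGT2B7 went from 1 to 10.7 units and GSTA2 from 3.63 to 10.4. GAPDH and ACTB, used as reference levels, differed by -0.07 and -0.09 (local SD 0.21 for both), with other GAPDH probes at 0.05 and 0.10.

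Lists of cholesterol synthesis, lipogenesis, apoptosis, interferon response and hypoxia had medians inside the range of random lists. For cholesterol synthesis the median was 0.13 (percentile 93.4), with 15 of 23 genes higher and 1 past 2-fold. That gene was SREBF2, above the floor in OA only and at least 1.47-fold higher, while SREBF1 differed by 0.54, HMGCS1 by -0.37 and IDI1 by -0.26. Lipogenesis genes had a median of -0.14 (percentile 6.41), with 12 higher and 18 lower of 31, 1 of them 2-fold higher and 2 lower, or 0 and 1 with values raised to the floor. CPT1A, which carries fatty acids into mitochondria, differed by 0.54 and MLXIPL by -1.01, CIDEC was at least 1.53-fold lower and FABP1 went from 1 to 10.3 units. Apoptosis regulators had a median of 0.04 (percentile 64.2), or -0.11 with values raised to the floor. Of 30 genes 5 were 2-fold higher and 2 lower, or 1 each way with values raised to the floor, and BAK1 was at least 1.23-fold higher and BCL2L11, which encodes BIM, at least 2.04-fold lower. Interferon response genes had a median of -0.01 (percentile 40.0), with 15 higher and 16 lower of 31 and 3 past 2-fold each way, or 1 higher and 2 lower with values raised to the floor. IFIH1, a sensor of viral RNA, was at least 1.52-fold higher and IFITM1 at least 1.92-fold lower. RSAD2 went from 4.07 to 11.9 units, at least 1.05-fold higher. Hypoxia and glycolysis genes had a median of -0.07 (percentile 23.4), with 12 higher and 21 lower of 33 and 0 past 2-fold. VEGFA differed by 0.92, while a dimmer probe went from 14.8 to 7.08 units, under the OA floor, and ANGPTL4 by 0.36, CA12 by -0.50 (second probe -0.22) and EGLN1 by -0.77.

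Lists of signalling targets, lysosomes, metal response and histones also lay inside the range of random lists. Autophagy and lysosome genes had a median of 0.03 (percentile 79.4), with 19 higher and 15 lower of 34 and 1 that was 2-fold lower. NEU1 differed by 0.86, ATG7 by 0.80, ATP6V1C1 by -0.87 and MCOLN1, a lysosomal calcium channel, by -1.11. Metallothionein and zinc genes had a median of 0.14 (percentile 87.6) and a mean of -0.05, with 5 higher and 4 lower of 9. SLC30A1, a zinc exporter, differed by -0.95, with a second probe at -0.44, and MT1H and MT1G, at 0.93 and 0.87, are near-identical copies whose probes can share signal. TGF-beta response genes had a median of -0.09 (percentile 20.5) and a mean of 0.09, or 0.02 with values raised to the floor, with 10 higher and 13 lower of 23. TGFBR2, the type II receptor, differed by -0.72 (local SD 0.29), with a second probe at -0.69, and JUNB was at least 1.56-fold higher. The last TGFBR2 probe was dim and went the other way, from 4.91 to 15.9 units. YAP and actin targets had a median of -0.09 (percentile 16.9), with 10 higher and 16 lower of 26 and 1 that was 2-fold lower, or 0 with values raised to the floor. LATS2 differed by 0.66, TAGLN by 0.54 and TGFB2 by -0.67, and F3, the tissue factor gene, was at least 1.82-fold lower. Replication-dependent histone genes lay above the floor for 15 of 25 genes, with a median of -0.10 (percentile 25.9), and 6 of the 15 were higher and 9 lower. H2BC21 differed by 0.66 and H2BC11 by 0.57, H3C2 was at least 1.88-fold lower and H2BC4 at least 1.44-fold lower. Markers of blood, endothelial and stellate cells lay above the floor for 7 of 24 genes, with a median of 0.34 (percentile 76.9). CD68 differed by -0.17, with a second probe at 0.14, CD79A differed by 0.10, and ALAS2 went from 4.49 to 10.7 units. PTPRC, a leukocyte gene, went from 1.89 to 24.0 units, at least 2.12-fold higher, while its other 3 probes were under the floor on both arrays.

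**Figure D3:**
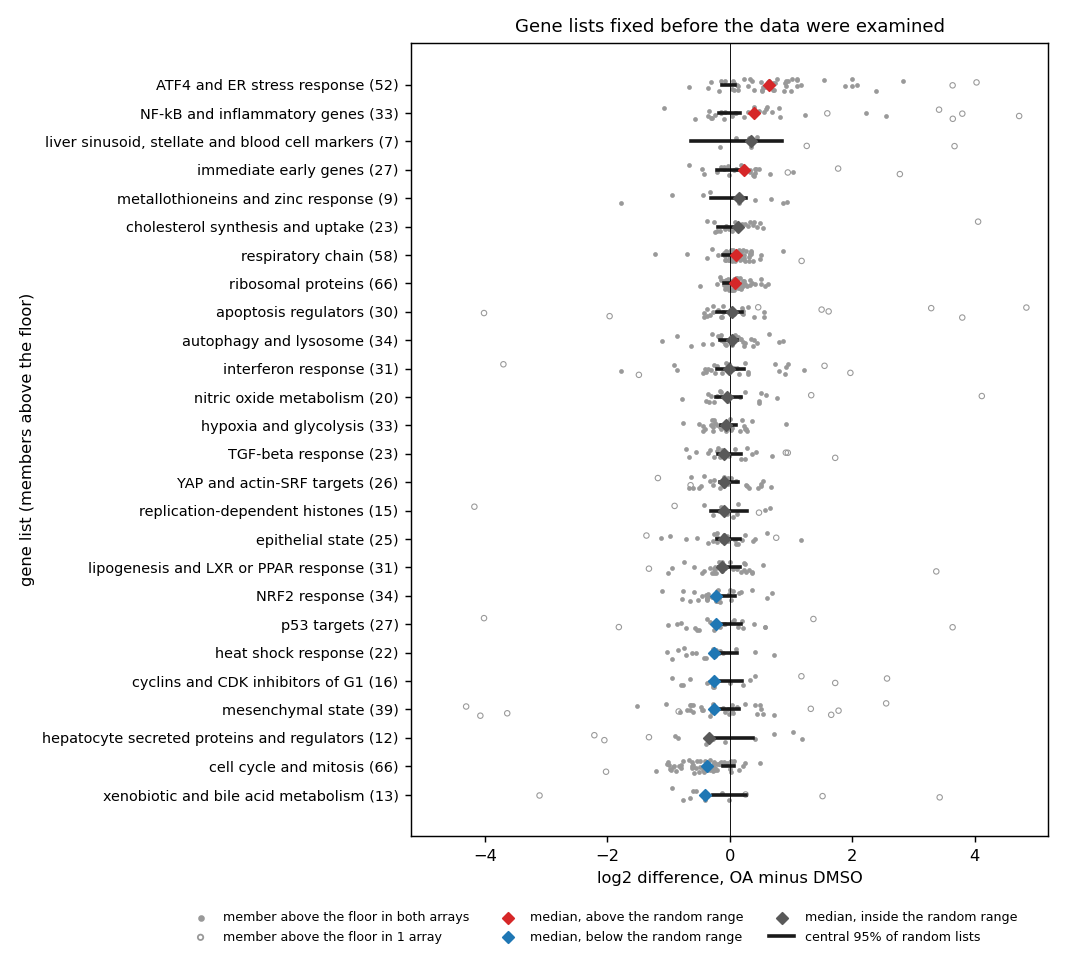
For each of the 26 gene lists (y axis, number of members above the floor in brackets), small points are the log2 differences of its members (x axis, OA minus DMSO), diamonds their medians and black bars the central 95% of 10000 random lists; open points lie above the floor in 1 array. The ATF4 list at 0.63 lies farthest above its bar, and the cell cycle list at -0.38 lies below its bar.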

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

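With 1 array per condition no replicate could be left out, and dim signal is what limits the single genes. Of the 26 list medians, 12 were called, and 8 of these kept their call under each of the 14 alternatives: the ATF4, NF-kB, immediate early, ribosomal and respiratory chain lists (higher), and the cell cycle, NRF2 and heat shock lists (lower). The ATF4 value ranged from 0.55 to 0.82 and the cell cycle value from -0.43 to -0.34, where 0.82 and -0.43 are list means. The NF-kB value ranged from 0.09, the median with no floor, to 0.78, the list mean. With no floor its percentile was 97.58, so that call was barely kept. Repeating the quantile normalization moved nothing, since the deposited values were already normalized that way.

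The counts of 2-fold genes, 994 higher and 828 lower, depended on the floor and on how dim values were treated. With the median of each array as the floor they were 1558 and 1578, and with no floor 2528 and 2486. Above the floor in both arrays they were 146 and 199. With values under the floor set to the floor they were 245 and 336, with 32 added to each linear value 34 and 15, and with a floor of 100 units 39 and 44. They were 45 and 30 for 2-fold and beyond 3 local robust SDs, and 1748 and 1611 at 1.5-fold. The loess gave 364 higher (971 lower). The SD of the differences rose from 0.44 to 0.50 with the median as the floor. Apart from the lower threshold, the unequal floors and the changed number of genes tested, the cause was not tested.

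The mesenchymal median lost its call with the median floor (-0.19), no floor (0.00) and the mean (-0.30). The xenobiotic and p53 lists lost it with the mean (-0.18 and -0.20). The G1 list lost it with no floor (-0.13) and with the mean or median over probes (-0.22 for both), and had the other sign with the mean over members (0.11). That sign rests on differences from values under the floor, since the mean with values raised to the floor was -0.14, also without a call. With that mean, which was added after the data were seen, the mesenchymal (-0.22) and xenobiotic (-0.50) lists kept their call and the p53 list (-0.20) just missed it at percentile 2.56. The hepatocyte list gained a call with no floor (-0.073), the mean over probes (-0.56) and the added 32 units (-0.22). Cholesterol synthesis gained one with the median over probes (0.19), and lipogenesis (-0.23), hypoxia (-0.16) and metallothioneins (0.41, 5 genes) with the floor of 100 units. Of 1064 recomputed values of 133 named genes, 987 moved by less than the local SD and 73 by more. The other 4 reversed: VAV3 (0.17, mean of probes), CHORDC1 (1.23, mean and median of probes) and PTPRC (-0.24, median of probes). For VAV3 and CHORDC1 a dim probe at 1 in DMSO pulled the value. For PTPRC the value is the gap between the 2 floors, since its other probes were under both. Genes above the floor in 1 array were recomputed with values raised to the floor and compared with the highest local SD, 0.69. A change of sign counted as a reversal only where the main log2 difference was 1 or more in size. Many of the 1064 values could not move. Repeated quantile normalization and raising values to the floor left these genes as they were, and the choice of probe changes nothing for a gene with 1 probe. The 987 is thus no measure of how stable single genes are.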

Other observations

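The tests of dim probes in the ATF4 and cell cycle lists, of the chaperone genes, of the ATF4-target synthetases and of second probes of genes under 2-fold were chosen after the result was seen, and the other tests before their result was seen. Genes with 100 units or more on either array, chosen after their values were seen, are listed here, by no test of a group. Higher in OA were CBS, of cysteine synthesis, at 1.75, TSC22D3, a glucocorticoid-induced gene, at 1.70, EIF4EBP1, a repressor of translation, at 1.46, SMOX, spermine oxidase, at 1.42, and PYCR1, of proline synthesis, at 1.23. S100P differed by 2.02, SNORC by 1.75 and RBCK1 by 1.53. Lower in OA were HPGD, the enzyme that inactivates prostaglandins, from 506 to 165 units (log2 -1.62), and the matrix or secreted protein genes SPOCK1 at -1.47, OLFML3 at -1.39 and VCAN at -1.12. AXIN2, a target of Wnt signalling, differed by -1.17 and PCSK5 by -1.18. Among the 17202 probes without a gene name, 1547 had 100 units or more on either array, of which 10 were 2-fold higher and 4 were 2-fold lower in OA.

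The ATF4 and endoplasmic reticulum stress list had members that stood apart. Its 17 measured endoplasmic reticulum chaperones and degradation factors had a median of 0.073 at percentile 82.9, with 11 of 17 higher. They ranged from -0.67 for CALR to 1.10 for DNAJC3, and HSPA5, the main chaperone of that compartment, differed by 0.14. The other 35 members had a median of 0.90, above all 10000 random lists. The split was made on the values it describes, so it tests nothing.

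Among cytosolic tRNA synthetases, the 12 measured ones often listed as ATF4 targets were all higher in OA, between 0.06 (TARS1) and 1.10 (SARS1), with a median of 0.62. The 6 other cytosolic ones lay between -0.39 and 0.13, with a median of -0.05, so the medians differed by 0.66. Of the 12, 8 are members of the ATF4 list, so the comparison largely repeats that result. The 4 outside it lay between 0.26 and 0.65, with a median of 0.43, too few to decide on a response of the target set. The 15 mitochondrial synthetases had a median of -0.24 at percentile 3.54, which argues against a shift of all tRNA synthetases.

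Technical sources of the higher ATF4 list were weighed. Among its 42 members with 100 units or more the median was 0.62, so the shift did not rest on dim members. These are most of the list's 52 members and were examined after its shift was seen, so this median describes the list and tests no cause. After the loess the list's median was 0.64, which argues against an intensity-dependent trend between the arrays as the source of the shift. The random lists were already matched on mean level, so the loess adds little. The second probes of 10 members had a median of 0.85, with 8 of 10 higher in OA, which argues against single probes that misread their gene. A difference between the cultures other than OA, such as density or spent medium, may produce the same response and stays open, since each group had 1 array and the labels do not say how many cultures it came from.

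The lower cell cycle list was weighed in the same way. The median was -0.38 among 58 members with 100 units or more and -0.37 after the loess. The second probes of 27 members had a median of -0.35, with 21 of 27 lower in OA, against -0.02 for all second probes. The values after the loess and at second probes argue against an intensity-dependent trend and misreading probes as sources of the shift. Here too the loess adds little to random lists matched on mean level. The 58 bright members are most of the list's 66, and were examined after its shift was seen. Their median shows that the shift did not rest on dim members, and tests no cause. With 1 array per group, from an unstated number of cultures, an effect of OA and a difference in growth between the cultures cannot be told apart, and both stay open.

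Most genes at 2-fold or more were dim (under 100 units here), and signal error of dim probes is a candidate explanation for many of them. Of 139 dim genes past 2-fold with a usable second probe, 82 (59.0%, exact binomial 95% interval 50.3 to 67.3) had a second probe that went the same way, and for 44 it was also 2-fold. Among dim genes under 2-fold the share was 56.2% of 889 (interval 52.9 to 59.5), so a second probe went the same way about as often without a 2-fold difference. Among genes with 100 units or more it was 20 of 27 past 2-fold (74.1%, interval 53.7 to 88.9) against 67.5% of 2005 under it. Second probes that were 2-fold the other way were not counted, so the 44 has no baseline. The test does not decide how many dim differences are real.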
